A study of Mus musculus with 3 samples.

How the data were processed

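Single-nucleus RNA sequencing (10x Genomics) was analysed in 3 libraries of brain nuclei from C57BL/6 mice. Per the labels, neurons labelled retrogradely from the lumbar spinal cord were dissected under fluorescence from sagittal slices, frozen, homogenised, and sorted as nuclei by flow cytometry. The deposited values are UMI counts per gene and barcode, made by the authors with Cell Ranger. The file headers name version 6.1.1 and the submitters' processing notes name version 7.0.1 with the mouse build mm10, and which of the versions made the counts was not settled. Whether introns were counted, whether counting used strand, and how barcodes were selected are not given in the sources used here. The files hold 32285 genes, and the smallest barcode in each library had 502, 500 and 501 UMIs. If nuclear RNA was counted over exons alone, long genes with much unspliced RNA would be measured at a lower level than if introns were counted.

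Barcodes were kept with at least 1000 genes and at most 5% mitochondrial UMIs. Doublets were called within each library with Scrublet (Scanpy 1.11.5) at an expected rate of 6% and removed, which marked 0.821%, 2.82% and 1.68% of the barcodes within these limits in replicates 1, 2 and 3. Counts were scaled to 10000 per nucleus and log transformed, 2000 variable genes were chosen within libraries, and 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1 (leidenalg 0.10.2). A first pass removed clusters named as non-neuronal, and a second pass gave 21 clusters of the remaining nuclei, which are called neuronal here. Variable genes came from a random part of the genes plus the cell type markers, never from the tested gene lists. The remaining 16319 genes were held out, and only they are counted or named as results, because the genes that define a cluster differ by construction.

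Each cluster was first given the 1 of 24 marker lists with the largest mean log2 ratio to the 25th percentile of clusters. It took that name when at least 3 of its markers were detected, at 5 CPM or more and at least 4 times the 25th percentile of clusters. The third-ranked of its markers also had to lie among the 250 leading genes, its median depth could not lie under 1/3 of that of its library, and no other class could hold more markers among its 10 leading genes. A corticospinal name needed Fezf2 or Crym. A further condition on 1 marker, and the results that rest on some other genes, are not reported here. The marker lists, the 15 gene lists, their tests and the alternatives listed here were fixed before the data were examined. The naming thresholds were set after the data had been seen, and so were the alternative limit of 500 leading genes and the alternative that adds unnamed clusters with at least 20 nuclei per library as classes. Clusters of paraventricular and lateral hypothalamus were joined as hypothalamus-like, and hindbrain clusters of both marker lists as hindbrain glutamatergic-like. Shares have exact 95% binomial intervals (Clopper-Pearson), which cover counting error only.

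UMIs were summed per library and class, for the 4 classes with at least 20 nuclei in each library. These 12 sums held between 516757 UMIs (hypothalamus-like, replicate 1) and 44751179 UMIs (corticospinal-like, replicate 2). They were fitted together with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM normalisation, the filterByExpr filter on low counts and the library as a block, leaving 6 residual degrees of freedom. Each class was compared with the equally weighted mean of the other 3 on the log scale. A log2 fold change can therefore differ from the ratio of the mean CPM, and among 191 named results its sign differed from that ratio in 2, which are not named. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 15759 tested genes and an absolute log2 fold change of at least 1, and the common biological coefficient of variation was 0.0729. Standard errors were approximated as the log2 fold change divided by the square root of the F statistic. A gene with 0 UMIs in a class is given as a bound against 3 counts over the class, and one with 1 to 3 UMIs as a ratio with its counting interval. Levels, bounds and ratios of the named genes use the TMM scale of the fit, and their levels by cluster were added after the results were seen.

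The 15 fixed gene lists were voltage-gated sodium channels, potassium channels (voltage-gated and sodium-activated), voltage-gated calcium channels with HCN channels, ionotropic glutamate receptors, GABA-A and glycine receptors, monoamine and acetylcholine receptors, neuropeptides, neurofilament and large projection neuron genes, growth-associated and regeneration-associated genes, neurotrophic and growth factor receptors, receptors for myelin and proteoglycan growth inhibitors, axon guidance receptors, classical cadherins, developmental transcription factors, and Hox genes outside the markers. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over 60 tests of 15 lists in 4 classes, and with an estimated correlation as an alternative. With fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, all 17 list calls of camera passed in the same direction, and 48 of the 60 tests passed in all. Members were also adjusted over the list alone. Named genes were the 10 largest increases and 5 largest decreases among held-out genes called in a comparison, at 20 CPM or more on the higher side and in the same direction in every library, plus 2 to 4 called members with the smallest p of each list that was called or had at least 3 called members. Predicted, Rik, mitochondrial and ribosomal protein genes were left out by this rule, and the text names a part of the genes it gives.

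The library served as a block because every class of a library came from the same sorted suspension. Deviations from the class means correlated between classes of the same library at 0.0648 to 0.444 (median 0.192, 18 pairs, across genes) and between libraries at -0.350 to -0.0154 (36 pairs). Centring each class on its own mean pushes the values between libraries to the opposite sign of those of the same library. The negative values are therefore no separate evidence for the block. The fit was tested on simulated counts with known changes. Of genes changed 4-fold it recovered 95.9% of 97 in corticospinal-like, 80.4% of 92 in hypothalamus-like, 91.1% of 90 in red nucleus-like and 95.7% of 94 in hindbrain glutamatergic-like neurons, over 14786, 14767, 14756 and 14762 genes. Of genes changed 2-fold, which lie at the size threshold itself, it recovered 35.2% of 91, 24.2% of 91, 28.6% of 91 and 43.6% of 94 in the same order, so changes near 2-fold were mostly not called. There were 2, 1, 2 and 3 false calls. Apart from the planted changes, split evenly between up and down, all simulated classes had the same mean profile. These rates and false calls therefore do not test the normalisation or the contrast where classes differ in many genes, as the real classes did. In the same counts, which held no planned change of a list, camera gave an unadjusted p under 0.05 in 1, 0, 1 and 1 of 15 lists, and 1 of the 60 tests stayed under 0.05 after adjustment. Genes were drawn independently and without a library effect, so these counts do not measure the error of camera where genes are correlated.

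Alternatives were a fit without the block, DESeq2 1.42.0, DESeq2 size factors, no filter on low counts, a 2-group fit against the sum of all other named neurons, clustering resolutions of 0.5 and 2, variable genes from all genes, values centred within each library, limits of 500 and 2000 genes per nucleus, doublets kept, and each library left out. Gene positions are from GENCODE vM21 on GRCm38 (mm10), where 32235 of the 32285 gene identifiers were found. Noradrenergic-like and serotonergic-like nuclei fell short of 20 in at least 1 library and were given no test. Comparisons planned for inhibitory-like, other midbrain-like and Edinger-Westphal-like neurons were not made, since no cluster took those names in the main clustering.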

Results

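Nuclei were taken from the brains of uninjured C57BL/6 mice in which neurons had been labelled retrogradely from the lumbar spinal cord. Retrograde labelling marks the cell bodies whose axons reach the labelled site, so the sort aims at brain neurons with an axon in the lumbar cord. How many sorted nuclei fit that aim was not tested. Droplet-based single-nucleus RNA sequencing counted unique molecular identifiers (UMIs) per gene and nucleus. There were 3 libraries, labelled as biological replicates 1, 2 and 3 of 1 group. The number of animals behind each library and the tracer are not given in the sources used here. The p-values measure only how far differences between classes varied over these libraries, beyond shifts shared by all classes of a library. That spread may in part be technical.

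The libraries held 2710, 11094 and 3713 barcodes and 27435221, 74287112 and 60490064 UMIs for replicates 1, 2 and 3. At least 1000 genes and at most 5% mitochondrial UMIs were found in 2679, 2769 and 3579 barcodes. Removal of 160 doublets and 23 non-neuronal nuclei left 2650, 2688 and 3506 neuronal nuclei, 8844 in all. First-pass clusters of 152 and 40 nuclei were provisionally endothelial and pericyte or fibroblast. They did not meet the conditions for those names and were not removed as non-neuronal, so the nuclei called neuronal may include others. Their median depth differed between libraries, at 8264 UMIs per nucleus in replicate 1, 19446 in replicate 2 and 14342 in replicate 3.

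The first question was which classes of brain neurons project to the lumbar cord. Corticospinal-like neurons had the highest mean share of the named classes, with 43.4% ± 10.0 of neuronal nuclei (SD, n = 3 libraries). Hindbrain glutamatergic-like neurons followed at 27.9% ± 5.13. Red nucleus-like neurons made up 4.35% ± 1.38 and hypothalamus-like neurons 2.44% ± 0.935. Noradrenergic-like and serotonergic-like nuclei were rare, at 0.505% ± 0.183 and 0.399% ± 0.121. The order of both large classes depended on the library and on the clustering. In replicate 1 there were 844 corticospinal-like and 867 hindbrain glutamatergic-like nuclei, and at clustering resolution 2 the mean shares were 24.9% and 27.9%, with 39.5% of nuclei unnamed there. With the naming limit at the 500 leading genes, chosen after the data were seen, replicate 1 held 41.8% corticospinal-like and 32.7% hindbrain glutamatergic-like nuclei. In the main clustering no cluster was named inhibitory-like, other midbrain-like or Edinger-Westphal-like. With variable genes from all genes, however, an inhibitory-like class held 5.38% of nuclei, and the hindbrain glutamatergic-like share was 22.5%. The fluorescence-guided dissection, the sort and the depth of each library can all set these shares.

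Composition differed between the libraries, and each library lay outside the counting intervals of both others for both large classes. The corticospinal-like share was 31.8% in replicate 1 (exact 95% binomial interval 30.1 to 33.7), 50.4% in replicate 2 (48.5 to 52.3) and 47.8% in replicate 3 (46.1 to 49.5). Hindbrain glutamatergic-like nuclei made up 32.7% (30.9 to 34.5), 22.5% (20.9 to 24.1) and 28.5% (27.0 to 29.99). The largest corticospinal-like cluster differed between the libraries. It was cluster 2 in replicate 1 with 336 nuclei, cluster 1 in replicate 2 with 944 and cluster 0 in replicate 3 with 877.

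**Figure D1:**
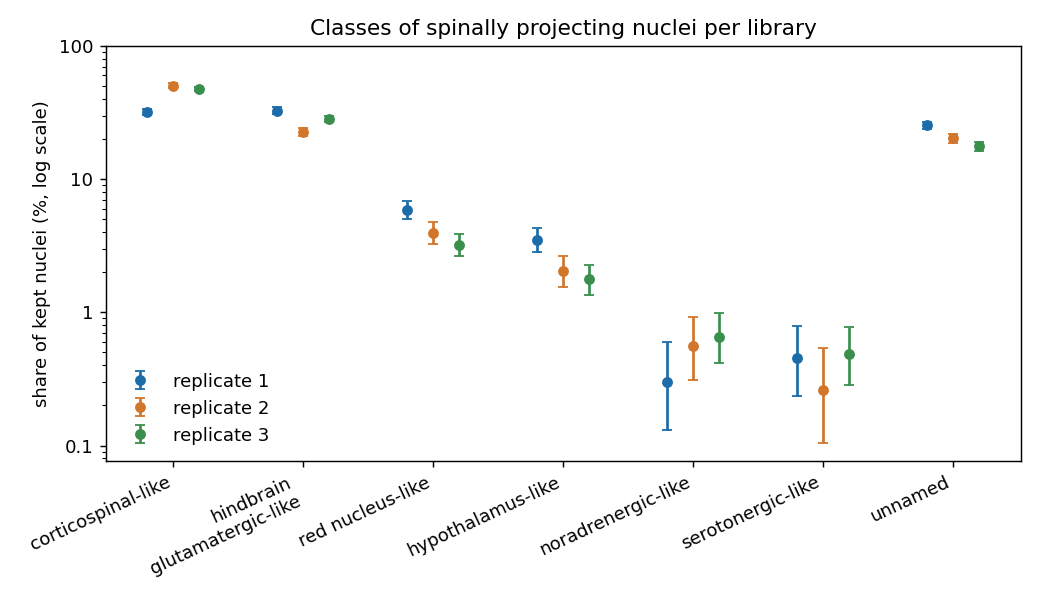
Share of each class among neuronal nuclei (vertical axis, percent) in the 3 libraries, with exact 95% binomial intervals as error bars. Corticospinal-like nuclei made up 31.8% to 50.4% and unnamed nuclei 17.6% to 25.3%.

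The names rest on marker genes fixed beforehand. In corticospinal-like neurons Bcl11b, a transcription factor of subcerebral projection neurons, reached 219.6 ± 13.6 CPM and Fezf2 28.5 ± 2.64 CPM. Sim1, a factor of the paraventricular nucleus, stood at 229.6 ± 71.4 CPM in hypothalamus-like neurons, and Hcrt, which encodes orexin, at 1358 ± 211 CPM. Red nucleus-like neurons carried Pou4f1 at 22.9 ± 6.67 CPM and Ttc6 at 121 ± 7.24 CPM. All 5 hindbrain clusters were named from markers of V2a neurons, a type of excitatory interneuron, and carried Lhx4 at 39.0 ± 4.10 CPM and the vesicular glutamate transporter Slc17a6 at 117 ± 8.86 CPM (SD, n = 3 libraries each).

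Unnamed clusters held 25.3%, 20.3% and 17.6% of neuronal nuclei in replicates 1, 2 and 3. The thresholds for a name were set after the data were examined. Markers ranked below the 250 leading genes kept 3 clusters out, with 18.3%, 3.57% and 9.53% of nuclei. Low depth kept out 1 cluster with 0.0755%, 8.33% and 0.0856%. Corticospinal markers without Fezf2 or Crym kept out 1 with 1.17%, 0% and 1.25%, and leading genes of another class kept out 1 with 2.08%, 1.41% and 1.65%. The remaining unnamed cluster, cluster 6, held 3.66%, 6.96% and 5.08%.

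Neuropeptide transcripts also appeared outside their own class. Hcrt had a UMI in 100% of nuclei of the lateral hypothalamus cluster, at 3371 CPM (UMIs scaled to a common total) and a median depth of 8291 UMIs, and in 55.3% of corticospinal-like nuclei, at 51.0 CPM and 20152 UMIs. Oxt, which encodes oxytocin, had a UMI in 23.8% of the paraventricular cluster at 533 CPM and 6111 UMIs, and in 15.6% of corticospinal-like nuclei at 7.70 CPM. Cortical neurons should lack both genes, so these values in them give the level of free RNA for these genes. Hcrt also stood at 67.9 ± 42.5 CPM in hindbrain glutamatergic-like and 61.7 ± 30.6 CPM in red nucleus-like neurons (SD, n = 3 libraries). Levels up to that size in a class therefore lie within the reach of free RNA where another class holds the gene at a far higher level. That size rests on Hcrt, a gene of a small cluster, and is no upper limit for other genes. The corticospinal marker Crym stood at 52.5 ± 14.4 CPM in corticospinal-like cluster 0 and 4.97 ± 3.23 CPM in hindbrain cluster 3, a larger part than for Hcrt. Whether that part is free RNA was not tested.

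The second question was how the transcripts of the 4 main classes differed. Each class was set against the mean of the other 3 within each library, over genes held out of the clustering. Levels are means of the class sums in CPM with the SD over n = 3 libraries, first in the class and then in the other 3 classes. Every gene named as higher or lower differed in the same direction in 3 of 3 libraries. A class with a very low level of a gene lowers the reference of every other class. Corticospinal-like neurons were such a class for Kcnc2, Unc5d, Dcc, Grin3a, Htr2c and Glra1. Rises of these genes in other classes therefore in part restate that low level. Gene lists were tested with camera, and of 17 list calls only 1 held with an estimated correlation between genes. For some lost calls the estimate lay below the preset of 0.01. Examples are potassium channels in hypothalamus-like (-0.00658) and calcium and HCN channels in hindbrain glutamatergic-like neurons (-0.0322). There the loss cannot come from correlated members, and its cause was not tested. Where 0 members of a list are given as called in a direction (edgeR), 0 to 8 members lay in that direction at an unadjusted p under 0.05, whatever their size. Where no range is given for a list, its p with an estimated correlation was the highest over 7 alternatives, and the lowest ran from 2.02e-10 to 0.0197 over these lists.

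**Figure D2:**
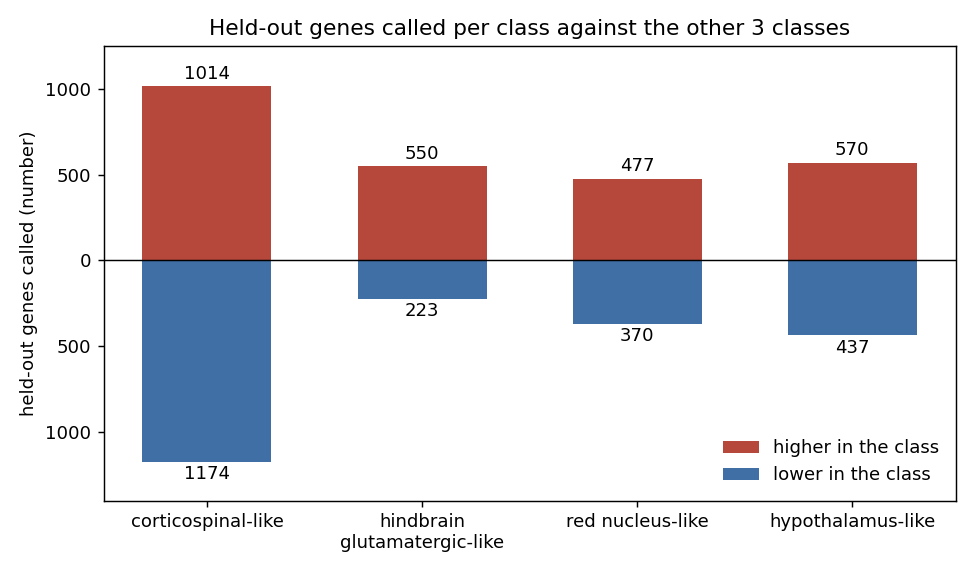
Number of held-out genes higher and lower in each main class than in the mean of the other 3 classes (adjusted p under 0.05 and an absolute log2 fold change of at least 1, edgeR), of 8066 tested. Corticospinal-like neurons had the most, with 1014 higher and 1174 lower.

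Corticospinal-like neurons had the most held-out genes called of the 4 classes. Nfib, a nuclear factor I protein of forebrain development, stood at 1242 ± 141 CPM against 33.7 ± 8.23 CPM (log2 fold change 5.21, SE 0.10). Its relative Nfix stood at 126 ± 8.92 CPM against 4.75 ± 2.40 CPM (4.69), and Tox, a high mobility group factor, at 968 ± 126 CPM against 45.7 ± 5.02 CPM (4.57). The phospholipid flippase gene Atp8b1 reached 57.9 ± 4.96 CPM against 1.52 ± 0.467 CPM and Kcnip3, which encodes a Kv4 channel-interacting protein, 178 ± 14.9 CPM against 4.31 ± 2.08 CPM. The largest decrease among genes at 20 CPM or more was in Kcnc2, a subunit of fast Kv3 potassium channels, at 4.89 ± 1.95 CPM against 753 ± 110.1 CPM (-7.04, SE 0.17). The calmodulin-dependent kinase gene Camk2d (-6.15), the homeobox gene Zfhx4 (-6.10), the neuregulin receptor gene Erbb4 (-6.03) and Tshz2 (-5.89) were also lower. In these 10 genes the adjusted p was at most 1.47e-19 (edgeR), and 1014 of 8066 held-out genes were higher and 1174 lower.

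Receptors for myelin and proteoglycan growth inhibitors were higher as a list in corticospinal-like neurons. Of 9 measured members 5 were higher, 0 lower and 4 did not pass the test, with the same counts adjusted over the list alone (camera adjusted p = 0.000157; adjusted p = 0.0927 with an estimated correlation). The Nogo receptor relatives Rtn4rl1 and Rtn4rl2 stood at 58.8 ± 12.8 CPM against 11.4 ± 0.884 CPM and 14.8 ± 1.69 CPM against 0.320 ± 0.335 CPM. Ptprd, a receptor phosphatase best known for synapse organisation, stood at 8757 ± 1164 CPM against 2543 ± 548 CPM (1.98).

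Potassium channels were also higher as a list, with 7 of 21 members higher and 2 lower, and likewise adjusted over the list alone (adjusted p = 0.0109; adjusted p = 0.0927 with an estimated correlation). The sodium-activated channel gene Kcnt2 reached 462 ± 75.7 CPM against 44.7 ± 7.68 CPM and Kcnh7 3406 ± 636 CPM against 402 ± 72.4 CPM, while Kcnc2 lay far lower. Calcium and HCN channels had 5 of 15 higher and 2 lower, also over the list alone (adjusted p = 0.0343; adjusted p = 0.128 with an estimated correlation). The calcium channel genes Cacna1e (2.10) and Cacna2d3 (2.77) were among those higher. The calcium and HCN call was lost without replicate 2 (adjusted p = 0.0923) and with no filter on low counts, and its adjusted p ran from 0.00501 to 0.187 over 7 alternatives. Axon guidance receptors had 9 of 26 higher and 4 lower, the same over the list alone (adjusted p = 0.0189; adjusted p = 0.0927 with an estimated correlation). The semaphorin co-receptor gene Nrp1 stood at 376 ± 60.8 CPM against 20.6 ± 3.65 CPM, whereas the netrin receptor genes Unc5d and Dcc stood at 6.28 ± 0.605 CPM against 385 ± 110.2 CPM and 35.3 ± 16.2 CPM against 1674 ± 397 CPM.

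The other lists passed no list test in corticospinal-like neurons, although single members differed. Except in the Hox list, the counts were the same adjusted over the list alone. Glutamate receptor genes had 6 higher and 5 lower of 16, with Grin2a at 1903 ± 154 CPM against 316 ± 17.5 CPM and Grin3a at 13.6 ± 1.06 CPM against 284 ± 35.6 CPM (list adjusted p = 0.225). GABA-A and glycine receptor genes had 7 higher and 4 lower of 17, with Gabra4 higher (3.26) and the glycine receptor gene Glra1 lower (-4.59; list adjusted p = 0.0972). Monoamine and acetylcholine receptor genes had 7 higher and 4 lower of 20, with the muscarinic Chrm3 (3.71) and serotonergic Htr1f (2.88) higher and Htr2c lower (-4.43; list adjusted p = 0.20). Sodium channels had 2 higher and 3 lower of 9 (adjusted p = 0.907), and Scn9a stood at 18.8 ± 5.52 CPM against 323 ± 32.5 CPM. Neuropeptide genes had 0 higher and 4 lower of 10 (adjusted p = 0.30), among them Scg2 (-2.29) and Penk (-2.29). With nuclei of 500 genes or more the Penk difference turned to 0.045 on the log2 scale (adjusted p = 0.928, from 1.27e-12 upward over all alternatives), and Scg2 fell short of the threshold of size (-0.94). Hypothalamus-like neurons, which held both genes at higher levels, were missing from the other classes in that fit. The nuclei and the reference therefore both changed. Growth-associated genes had 2 higher and 2 lower of 17 (adjusted p = 0.748), with the kinase gene Dclk1 higher (1.55) and Sox11 lower (-3.59). Growth factor receptors had 3 higher and 4 lower of 17 (adjusted p = 0.762), cadherins 4 and 2 of 13 (adjusted p = 0.665) and developmental transcription factors 12 and 13 of 36 (adjusted p = 0.478). Neurofilament genes had 0 higher and 2 lower of 11 (adjusted p = 0.80). Of 2 Hox genes 1 was lower over all genes, Hoxd3 (-2.31), and 0 over the list alone (adjusted p = 0.880). The glutamate and GABA lists tested upward with positive medians (0.48 and 0.59) and negative means (-0.20 and -0.03), the transcription factors tested upward with a median of -0.18, and the sodium channels tested downward with a median of 0.17. Neurofilament genes tested downward with a median of 0.01, growth-associated genes upward with a mean of -0.15 and growth factor receptors upward with a median of -0.28. With no filter on low counts, 1527 genes were higher.

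**Figure D3:**
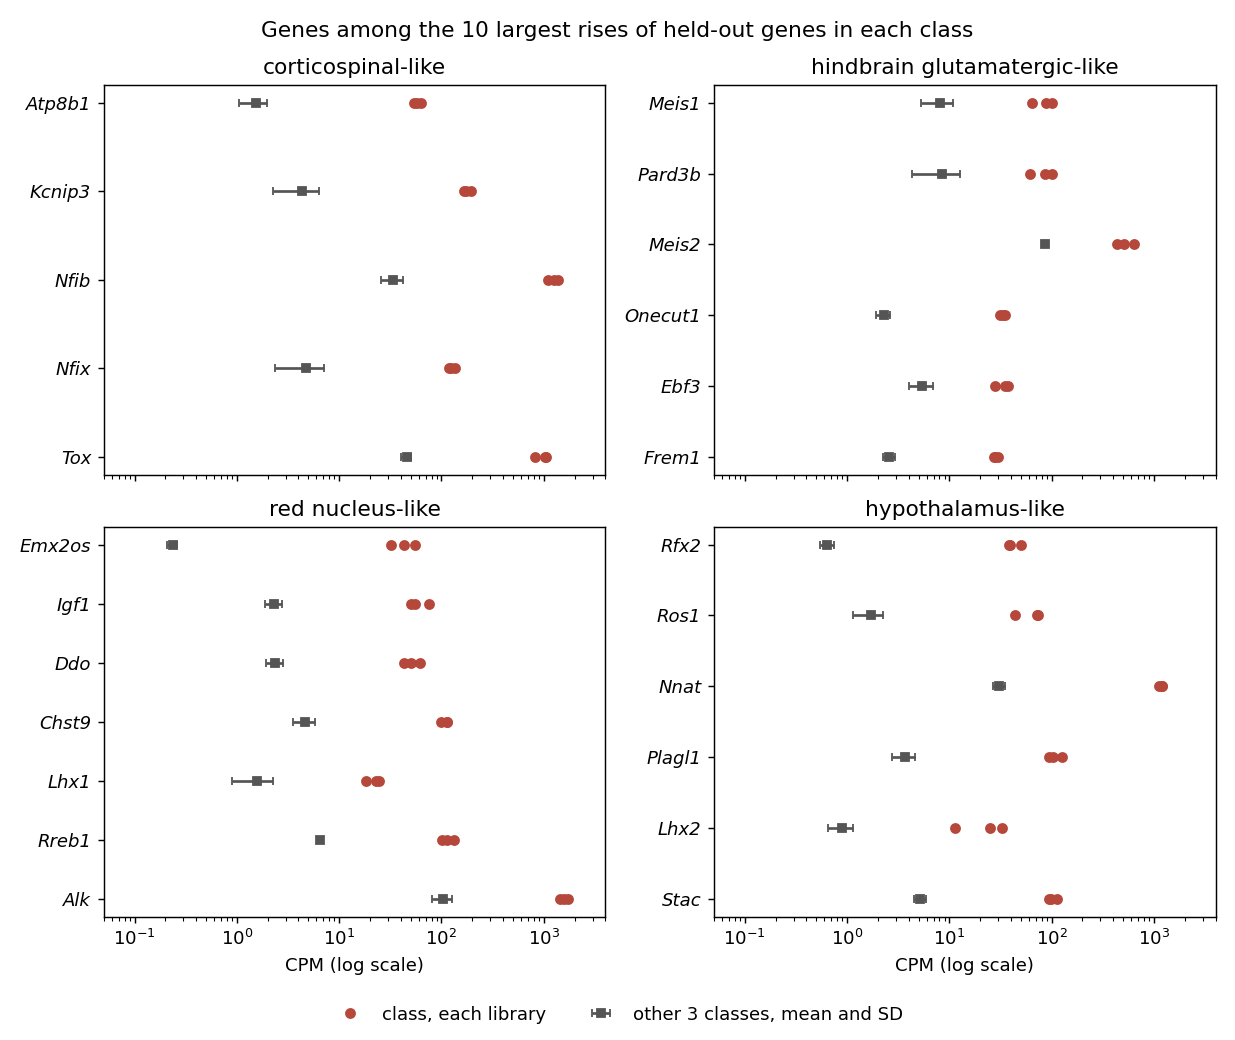
Levels in CPM (horizontal log axis) of genes named in the text among the 10 with the largest positive log2 fold change in each class, from held-out genes at 20 CPM or more. Red points are the class in each of the 3 libraries and grey squares the mean of the other 3 classes with the SD; Nfib stood at 1242 ± 141 CPM in corticospinal-like neurons.

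In hypothalamus-like neurons Nnat, an imprinted gene that encodes neuronatin, stood at 1170.3 ± 53.3 CPM against 30.8 ± 4.34 CPM (log2 fold change 5.30, SE 0.09), and Plagl1, an imprinted zinc finger gene, at 108 ± 16.2 CPM against 3.67 ± 0.929 CPM (5.05, SE 0.18). The receptor tyrosine kinase gene Ros1 stood at 63.0 ± 16.4 CPM against 1.70 ± 0.544 CPM, the transcription factor gene Rfx2 at 42.4 ± 6.80 CPM against 0.642 ± 0.101 CPM, Stac at 102 ± 9.60 CPM against 5.19 ± 0.712 CPM and the LIM homeobox gene Lhx2 at 23.1 ± 10.7 CPM against 0.896 ± 0.241 CPM. Tshz2 (4.30) and Foxp2 (4.22) were also higher, at 614 ± 50.3 CPM and 855 ± 224 CPM. Meis2 was lower, at 12.6 ± 5.40 CPM against 258 ± 38.9 CPM (-3.17), and so was the cadherin gene Cdh8 (-3.02). In these 10 genes the adjusted p was at most 7.29e-08 (edgeR), and 570 held-out genes were higher and 437 lower.

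The class joins cluster 15, named from paraventricular markers, and cluster 17, named from lateral hypothalamic markers, with 143 and 67 nuclei, and several of these levels come mostly from 1 of them. Nnat stood at 311 CPM in cluster 15 and 2529 CPM in cluster 17, Rfx2 at 1.60 and 105, and Stac at 5.61 and 251 (UMIs over all libraries). Plagl1, at 3.21 and 280.1, and Ros1, with no UMI in cluster 15 and 164 CPM in cluster 17, were above the other classes in cluster 17 alone, as was Vgf. Foxp2, at 1319.7 and 32.8, was above them in cluster 15 alone, as were Penk, Htr2c and Unc5d. Of 52 named results in this class 40 had the direction of the class in both clusters.

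No UMI of the growth factor gene Igf1 was found in hypothalamus-like neurons, and the other classes held 22.5 ± 4.89 CPM, which makes it at least 15.3-fold lower than their mean against 3 counts over the class (adjusted p = 0.00263, edgeR). That mean is carried by red nucleus-like neurons, at 60.5 CPM, against 6.68 in hindbrain glutamatergic-like and 0.279 in corticospinal-like neurons. The corticospinal-like level lies under the 1.47 CPM of 3 counts, so Igf1 was not shown to be lower than there. Atp8b1 had 1 UMI, or 0.490 CPM over the class, against 20.6 ± 1.75 CPM, a ratio of 42.1 with a counting interval of 7.56 to 1663 (adjusted p = 0.00174). Here corticospinal-like neurons carry the mean, at 57.9 CPM against 2.35 in hindbrain glutamatergic-like and 1.62 in red nucleus-like neurons. Both calls were lost when unnamed clusters were added as classes, an alternative chosen after the data were seen (adjusted p = 0.0688 and 1). Over all alternatives the adjusted p ran from 0.000144 to 0.110 for Igf1, the highest with variable genes taken from all genes, and from 1.50e-27 to 1 for Atp8b1. Interval and bound cover counting error only.

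Neuropeptide genes were higher as a list in hypothalamus-like neurons. Of 10 measured 3 were higher and 0 lower, or 4 and 0 adjusted over the list alone (adjusted p = 0.00419; adjusted p = 0.108 with an estimated correlation). The granin gene Scg2 stood at 301 ± 38.8 CPM against 38.5 ± 5.87 CPM, Penk, which encodes enkephalin, at 17.8 ± 9.39 CPM against 2.44 ± 0.385 CPM, and Vgf at 26.7 ± 11.1 CPM against 13.7 ± 3.12 CPM. Without replicate 2 the list's call was lost (adjusted p = 0.0552, and 0.00343 to 0.108 over 7 alternatives). The Vgf difference lay close to the threshold of size and missed it under 10 of 16 alternatives, among them without replicate 1 (log2 fold change 0.86) and without replicate 2 (0.82).

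Neurofilament and large projection neuron genes were lower as a list, with 4 of 11 lower and 0 higher, or 5 and 0 adjusted over the list alone (adjusted p = 0.000355; adjusted p = 0.0817 with an estimated correlation). The median of the list was -0.92, also with Spp1, which had no UMI in the class, at its bound. The vesicle genes Syt2 and Sv2c stood at 24.7 ± 7.74 CPM against 120.4 ± 6.93 CPM and 13.0 ± 5.44 CPM against 37.7 ± 1.93 CPM. Potassium channels had 5 of 21 lower and 1 higher, also over the list alone (adjusted p = 0.00311; adjusted p = 0.0817 with an estimated correlation), with the M-current genes Kcnq3 (-1.58) and Kcnq5 (-1.60) lower and Kcnc2 higher (2.22). Growth inhibitor receptors had 2 of 9 lower, Ptprd (-2.03) and Rtn4rl1 (-2.66), and none higher, also over the list alone (adjusted p = 0.000376; adjusted p = 0.0817 with an estimated correlation).

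The remaining lists passed no list test in hypothalamus-like neurons. Developmental transcription factors had 7 higher and 13 lower of 36, or 7 and 14 adjusted over the list alone (adjusted p = 0.902). Monoamine and acetylcholine receptors had 2 higher, among them Htr2c (1.85), and 7 lower of 20, among them Chrna7 (-2.19), or 2 and 8 over the list alone (adjusted p = 0.524). Axon guidance receptors had 4 higher and 7 lower of 26 (adjusted p = 0.478), with Unc5d higher (2.90) and Epha4 lower (-2.55). GABA-A and glycine receptors had 5 higher and 3 lower of 17 (adjusted p = 0.431), tested upward with a median of -0.03, and Gabra2 was higher (1.48). Against the sum of all other named neurons Gabra2 stood at 0.57 and lost its call. The counts of axon guidance and GABA receptors were the same adjusted over the list alone. In the glutamate receptor list, tested downward with a mean of 0.01 (adjusted p = 0.0896), Grik1 was higher (3.07) and Gria3 lower (-2.63). Calcium and HCN channels tested downward with a median of 0.03, growth factor receptors upward with a median of -0.25, and the Hox list upward with a median of -1.81, or -0.07 with Hoxd4, at 0 UMIs, set at its bound. Against the sum of all other named neurons, 854 genes were lower.

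Red nucleus-like neurons carried high levels of genes of large projection neurons. Of 11 neurofilament and large projection neuron genes 6 were higher and 0 lower, with the same counts adjusted over the list alone (adjusted p = 6.11e-10; adjusted p = 0.0654 with an estimated correlation). Esrrg, which encodes an estrogen-related nuclear receptor, stood at 1126 ± 102 CPM against 406 ± 43.0 CPM (log2 fold change 1.51, SE 0.06), its relative Esrrb at 28.1 ± 1.40 CPM against 5.60 ± 2.30 CPM and the fast calcium sensor gene Syt2 at 201 ± 22.7 CPM against 61.5 ± 3.31 CPM. The receptor tyrosine kinase gene Alk stood at 1592 ± 139 CPM against 104 ± 22.4 CPM (4.37, SE 0.08). In these 4 genes the adjusted p was at most 8.20e-09 (edgeR).

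Other genes higher in red nucleus-like neurons were Igf1, at 60.5 ± 13.7 CPM against 2.32 ± 0.440 CPM, Chst9, a sulfotransferase gene, at 108 ± 8.76 CPM against 4.64 ± 1.14 CPM, Rreb1 at 116 ± 16.3 CPM against 6.51 ± 0.202 CPM, the D-aspartate oxidase gene Ddo at 51.7 ± 9.73 CPM against 2.38 ± 0.440 CPM and the LIM homeobox gene Lhx1 at 21.9 ± 3.33 CPM against 1.59 ± 0.690 CPM. The antisense transcript Emx2os stood at 43.6 ± 11.7 CPM against 0.236 ± 0.0261 CPM, but it overlaps the naming marker Emx2 on the opposite strand, and whether counting used strand is not given in the sources used here. The kainate receptor gene Grik3 was lower, at 2.48 ± 2.23 CPM against 54.8 ± 1.59 CPM, as were the natriuretic peptide receptor gene Npr3, at 1.29 ± 0.958 CPM against 43.7 ± 4.19 CPM, and the metabotropic receptor gene Grm8, at 54.3 ± 13.6 CPM against 748 ± 126 CPM. In these 9 genes the adjusted p was at most 6.93e-09 (edgeR). Of the held-out genes 477 were higher and 370 lower.

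Channel and receptor genes went both ways in red nucleus-like neurons, and the neurofilament list was the only one of 15 past the list test. The Kv3 subunit genes Kcnc1 and Kcnc2 stood at 139 ± 16.6 CPM against 53.1 ± 7.80 CPM and 1042 ± 179 CPM against 407 ± 49.8 CPM, and Kcnh7 was lower (-1.61), in a list with 3 higher and 4 lower of 21, also over the list alone (adjusted p = 0.478). The serotonin receptor gene Htr1d stood at 52.5 ± 7.33 CPM against 6.52 ± 1.19 CPM, while Htr1f (-2.21) and Chrm3 (-2.90) were lower (3 higher and 3 lower of 20, 3 and 4 adjusted over the list alone, adjusted p = 0.983). The GABA-A receptor genes Gabra2 (-2.32) and Gabrg3 (-2.30) were lower and the glycine receptor gene Glra3 higher (2.81; 1 higher and 4 lower of 17, 1 and 5 adjusted over the list alone, adjusted p = 0.0943). Ret, the receptor for glial-derived factors, stood at 23.0 ± 4.49 CPM against 5.03 ± 0.927 CPM, and Gfra2, a co-receptor of that family, at 1.74 ± 0.848 CPM against 26.2 ± 7.48 CPM. Calcb, which encodes a calcitonin gene-related peptide, stood at 8.32 ± 5.28 CPM against 0.136 ± 0.0690 CPM and had no UMI in 1 other class. Developmental transcription factors had 12 higher and 13 lower of 36, or 12 and 15 adjusted over the list alone (adjusted p = 0.923). Test, median and mean differed in sign in 8 lists. The transcription factors and growth factor receptors tested upward with medians of -0.42 and -0.03, the potassium channels and growth inhibitor receptors upward with means of -0.06 and -0.23, the monoamine receptors, cadherins and growth-associated genes downward with medians of 0.35, 0.15 and 0.14, and the neuropeptides downward with a mean of 0.10. Against the sum of all other named neurons, 792 genes were lower, and without replicate 1, 2 lists were higher and 1 lower.

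**Figure D4:**
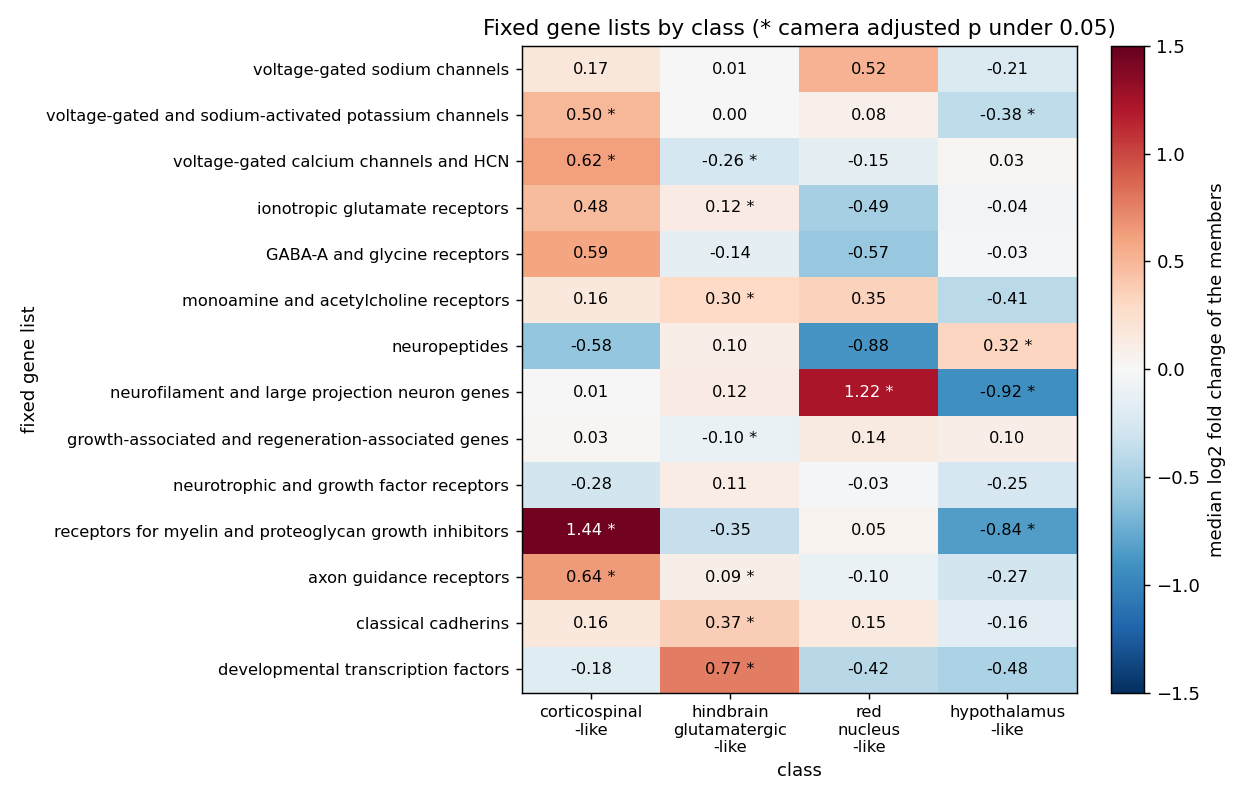
Median log2 fold change of the measured members of 14 gene lists (vertical axis) in each main class against the mean of the other 3 (horizontal axis), with a star where the camera adjusted p was under 0.05; the Hox list, with 2 measured genes, is left out. Neurofilament and large projection neuron genes had a median of 1.22 in red nucleus-like and -0.92 in hypothalamus-like neurons.

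Hindbrain glutamatergic-like neurons carried high levels of developmental transcription factors. Meis1 and Meis2, homeobox cofactors of Hox proteins, stood at 84.4 ± 18.6 CPM against 8.06 ± 2.78 CPM (log2 fold change 4.36, SE 0.16) and 525 ± 102 CPM against 86.9 ± 4.77 CPM (3.93, SE 0.10). Onecut1 stood at 33.4 ± 1.77 CPM against 2.28 ± 0.366 CPM, Ebf3 at 33.4 ± 4.95 CPM against 5.42 ± 1.43 CPM and Zfhx3 at 611 ± 113 CPM against 231 ± 28.4 CPM. Foxp2, another transcription factor gene, was lower, at 11.1 ± 0.862 CPM against 348 ± 93.3 CPM (-4.06). Of 36 measured developmental transcription factors 15 were higher, 8 lower and 13 did not pass the test, or 15 and 9 adjusted over the list alone (adjusted p = 1.86e-10). This list alone of the 17 list calls held with an estimated correlation (adjusted p = 0.0113). In the 6 genes named here the adjusted p was at most 8.81e-15 (edgeR).

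Both measured Hox genes outside the markers were higher, also over the list alone (adjusted p = 4.07e-06; adjusted p = 0.0817 with an estimated correlation). Hoxd3 stood at 19.9 ± 3.38 CPM against 0.664 ± 0.721 CPM and Hoxd4 at 5.94 ± 3.01 CPM against 0.0325 ± 0.0139 CPM, and the 2 overlap on the same strand, so that their counts may not be separable. Other genes higher were the polarity gene Pard3b, at 82.7 ± 19.7 CPM against 8.46 ± 4.16 CPM, and Frem1, at 28.4 ± 1.26 CPM against 2.58 ± 0.360 CPM. The cell adhesion gene Dscaml1 was lower, at 19.9 ± 6.00 CPM against 262 ± 17.1 CPM, as were Tafa1, at 269.6 ± 19.4 CPM against 2134 ± 278 CPM, and the AMPA receptor auxiliary gene Cnih3, at 7.97 ± 3.33 CPM against 70.5 ± 3.86 CPM. Of the held-out genes 550 were higher and 223 lower. Of 42 named results in this class 23 had its direction in each of its 5 clusters, against 50 of 50 in the 4 corticospinal-like clusters. In cluster 10 Onecut1, Ebf3 and Zfhx3 stood at 2.00, 0.182 and 164 CPM, under the mean of the other classes, and Pard3b, Grik1, Chrm2 and Drd2 were also under it there. Htr2c was under it in cluster 7, and Kit and Met in 3 clusters each.

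Of 6 receptor lists 3 were higher in hindbrain glutamatergic-like neurons, and so were the cadherins. Glutamate receptors had 5 of 16 higher and 1 lower (adjusted p = 0.00613; adjusted p = 0.224 with an estimated correlation), with Grik1 at 562 ± 119 CPM against 212 ± 27.3 CPM, Grin3a at 323 ± 51.4 CPM against 181 ± 18.4 CPM and Grin2a lower (-1.70). Monoamine and acetylcholine receptors had 6 of 20 higher and 3 lower (adjusted p = 0.00419; adjusted p = 0.0817 with an estimated correlation), with Htr2c at 669.7 ± 109 CPM against 386 ± 85.8 CPM, the muscarinic Chrm2 at 348 ± 55.6 CPM against 123 ± 12.6 CPM and the dopamine receptor gene Drd2 at 19.2 ± 3.14 CPM against 3.79 ± 1.25 CPM. Axon guidance receptors had 6 of 26 higher and 3 lower (adjusted p = 0.0184; adjusted p = 0.0927 with an estimated correlation), with Dcc at 2517 ± 636 CPM against 846 ± 184 CPM and Nrp2 at 78.6 ± 8.77 CPM against 14.3 ± 1.03 CPM. Cadherins had 3 of 13 higher, among them Cdh7 (1.50), and 2 lower, among them Cdh20 (-1.91; adjusted p = 0.000730; adjusted p = 0.0906 with an estimated correlation). The counts of these 4 lists were the same adjusted over the list alone. Corticospinal-like neurons, part of the mean set against this class, held Grin3a, Htr2c and Dcc at far lower levels than the other classes. The rises of these genes in part restate that. The axon guidance call was lost without a replicate block (adjusted p = 0.0897) and without replicate 2 (adjusted p = 0.152), and the monoamine call without replicate 2 (adjusted p = 0.132). With no filter on low counts the glutamate, monoamine, axon guidance and Hox calls were lost, and over 7 alternatives their adjusted p ran from 0.00599 to 0.476, 0.00343 to 0.132, 0.0171 to 0.852 and 1.89e-07 to 0.118.

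Calcium and HCN channels were lower as a list in hindbrain glutamatergic-like neurons, with 2 of 15 lower, Cacna2d3 (-1.52) and Cacna1h (-1.92), and none higher, also over the list alone (adjusted p = 0.00319; adjusted p = 0.0817 with an estimated correlation). With unnamed clusters added as classes Cacna2d3 stood at -0.77 and lost its call. Growth-associated genes were lower as a list with no single member called of 17, over all genes or over the list alone (adjusted p = 0.0478; adjusted p = 0.141 with an estimated correlation). At an unadjusted p under 0.05 (edgeR) 7 members were lower and 1 higher. That call was lost without a replicate block (adjusted p = 0.0806) and without replicate 1 (adjusted p = 0.0808), and its adjusted p ran from 0.00633 to 0.141 over 7 alternatives. GABA-A and glycine receptors had 4 higher and 0 lower of 17, also over the list alone, and passed no list test (adjusted p = 0.175), with a median of -0.14, a mean of 0.28 and an upward test, while potassium channels tested downward with a mean of 0.04. The glycine receptor gene Glra1 stood at 219 ± 37.3 CPM against 53.6 ± 2.91 CPM. Growth factor receptors had 3 higher and 0 lower of 17, also over the list alone (adjusted p = 0.478), among them Kit, at 11.9 ± 1.73 CPM against 1.06 ± 1.02 CPM, and Met, at 7.12 ± 1.36 CPM against 3.54 ± 0.3004 CPM. Hypothalamus-like neurons, part of that mean, had no UMI of Met. With nuclei of 500 genes or more Met was lower instead (log2 fold change -1.90, adjusted p = 0.00521), but there hypothalamus-like neurons were missing from the other classes. Against the sum of all other named neurons Met stood at 0.15 (adjusted p = 0.505, edgeR). Its adjusted p ran from 7.60e-07 to 0.505 over all alternatives. Growth inhibitor receptors had 0 higher and 2 lower of 9, also over the list alone, and a median of -0.35 (adjusted p = 0.141). The lower members, named after their values were seen, were Rtn4r (-1.31) and Rtn4rl1 (-1.97). The counts of genes higher and lower were 1317 and 1037 against the sum of all other named neurons, and 292 and 148 with variable genes taken from all genes. In that last fit an inhibitory-like class was among the other classes.

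Noradrenergic-like and serotonergic-like neurons were too few for the planned test, at 8, 15 and 23 and at 12, 7 and 17 nuclei in replicates 1, 2 and 3, so their values are given without one. They were chosen after the values were seen, as held-out genes at 100 CPM or more and over 2 times the main classes in each library. In noradrenergic-like neurons the monoamine oxidase gene Maoa stood at 554 ± 110.0 CPM against 18.3 ± 3.97 CPM in the main classes, the calcitonin receptor gene Calcr at 422 ± 94.9 CPM against 3.14 ± 1.50 CPM and Fgf13 at 1860.1 ± 209.9 CPM against 125 ± 27.0 CPM. In serotonergic-like neurons Trh, which encodes thyrotropin-releasing hormone, stood at 140.4 ± 118 CPM against 0.681 ± 0.256 CPM, and Lmx1b, a transcription factor of serotonergic neurons, at 115 ± 37.5 CPM against 1.00 ± 0.501 CPM (SD, n = 3 libraries).

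On the mm10 assembly Nfib (ENSMUSG00000008575) lies on chromosome 4 from 82290173 to 82705750 on the minus strand, Kcnc2 (ENSMUSG00000035681) on chromosome 10 from 112271121 to 112467024 on the plus strand, Nnat (ENSMUSG00000067786) on chromosome 2 from 157560078 to 157562522 on the plus strand, Alk (ENSMUSG00000055471) on chromosome 17 from 71868972 to 72604627 on the minus strand and Meis1 (ENSMUSG00000020160) on chromosome 11 from 18879817 to 19018985 on the minus strand. Hoxd3 lies on chromosome 2 from 74711927 to 74748442 on the plus strand and Hoxd4 on chromosome 2 from 74711929 to 74729160 on the plus strand, and Emx2os on chromosome 19 from 59425104 to 59458635 on the minus strand. The values count UMIs over each whole gene, so no exon or UTR can be named. Genes named above that share a strand and position with another annotated gene, so that their counts can be split or merged, include Nfib, Erbb4, Grin3a, Chrm3, Cdh8, Sv2c, Hoxd3 and Hoxd4.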

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

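The tests on clusters 5 and 12 and the comparisons of clusters 5, 6 and 14 with the main classes were chosen only after the results were seen, while the tests on the low-gene barcodes were planned before theirs. These results come from barcodes and clusters that the comparisons of named classes do not use.

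Replicate 2 held 8324 barcodes with under 1000 genes, against 31 in replicate 1 and 134 in replicate 3. They had a median of 679 UMIs and took 7.92% of the UMIs of replicate 2. Within strata of depth, a corticospinal and a hindbrain marker were detected in the same barcode with an odds ratio of 1.06 (95% interval 0.925 to 1.22), an interval that reaches 1, as droplets holding free RNA alone predict. Corticospinal-like and hindbrain glutamatergic-like nuclei of replicate 2 thinned to the same depths gave 0.467 with an upper end of 0.726, and the barcodes lie above that end. The thinned set held no other class and no unnamed nuclei, and nuclei that express neither kind of marker would raise the odds ratio. The test therefore cannot decide against single nuclei with few UMIs and no free RNA. Free RNA alone, shallow nuclei alone and a mixture of both stay open, and no biological explanation was tested, since the libraries form 1 group.

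Targets of the tumour suppressor p53 stood above the main classes in clusters 5 and 12, which held 552 and 321 nuclei. The test used only held-out targets that had not been viewed beforehand. In cluster 5 their median log2 ratio was 1.82 (SD 0.30, n = 3 libraries), with 5 of 6 measured targets above. A target counted as measured at 5 CPM or more in the cluster or in the main classes, a limit that leans upward, and over all 8 held-out targets the median was 1.26 (SD 0.0312), with 6 above. Gtse1 stood there at 17.8 ± 0.756 CPM against 0.308 ± 0.0773 CPM, Pmaip1, which encodes the cell death protein Noxa, at 8.78 ± 1.59 CPM against 0.568 ± 0.498 CPM, and Cdkn2aip below, at 9.31 ± 5.16 CPM against 18.0 ± 1.90 CPM. In cluster 12, whose nuclei had a median of 3844 UMIs, the median was 2.66 (SD 0.43), with 6 of 7 above (1.96 over all 8 targets, with 7 above), and the heat shock gene Hspa8 stood at 1266 ± 229 CPM against 91.4 ± 29.6 CPM.

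Clusters 5 and 12 took 264, 67 and 221 and 204, 17 and 100 nuclei from replicates 1, 2 and 3. In cluster 5 the p53 targets exceeded the pooled early response and heat shock genes by 1.14 in median log2 ratio (SD 0.43, n = 3 libraries), but the 2 kinds of gene differed there. The early response genes stood at a median log2 ratio of 1.62 (SD 0.49, 4 of 4 above) and the heat shock genes at 0.37 (SD 0.0146). The p53 targets exceeded the early response genes there by 0.21 (SD 0.72, n = 3 libraries) and the heat shock genes by 1.45 (SD 0.30). In cluster 12 the difference from the early response genes was -0.50 (SD 0.98) and from the heat shock genes 0.79 (SD 0.47). Over all held-out genes whatever their level the difference from the early response genes was -0.18 (SD 0.46) in cluster 5 and -1.21 (SD 0.40) in cluster 12, where that from the heat shock genes was 0.09 (SD 0.39). In neither cluster did the p53 targets exceed the early response genes by more than the spread between libraries, so transcription started during dissection and nuclear preparation and another source of the p53 targets cannot be told apart. The median in the replicate 2 nuclei of both clusters was 1.82 in log2 ratio, but nuclei were placed in the clusters by their expression, so this value does not bear on why replicate 2 gave fewer of them, and a difference between the libraries stays open. No biological explanation was tested, since the libraries form 1 group.

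Cluster 5 had 1417 of 7542 held-out genes higher than the mean of the main classes and 902 lower. Since this cluster was provisionally corticospinal, these counts may include genes by which corticospinal-like neurons differ from the other classes. Cluster 6 had 348 of 7542 higher and 217 lower, with those higher including Ebf1, at 1672 ± 411 CPM against 65.2 ± 11.9 CPM, Prdm6, at 123 ± 36.9 CPM against 0.580 ± 0.298 CPM, Dach1, at 919 ± 164 CPM against 158 ± 55.2 CPM, and Pde11a, at 155 ± 9.70 CPM against 9.22 ± 0.599 CPM (SD, n = 3 libraries). Cluster 14 had 450 of 7542 higher and 257 lower, with those higher including Meis1, at 244 ± 50.3 CPM against 28.6 ± 6.98 CPM, Ano1, at 56.1 ± 11.1 CPM against 0.941 ± 0.476 CPM, Tfap2a, at 26.3 ± 6.96 CPM against 0.135 ± 0.0496 CPM, and Mab21l2, at 52.3 ± 6.99 CPM against 3.18 ± 0.428 CPM (SD, n = 3 libraries). In these 8 genes the adjusted p was at most 3.11e-10 (edgeR), with the same direction in 3 of 3 libraries. Cluster 14 was provisionally hindbrain glutamatergic, so its counts may likewise include genes of that class. Meis1 was also higher in hindbrain glutamatergic-like neurons and is not particular to cluster 14.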

How the results depend on the processing

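The limit of 500 leading genes for a name and the addition of unnamed clusters as classes were chosen only after the results were seen. Of 191 named gene results, 160 kept direction and call under every alternative that gave a value. Over 3193 values under alternatives, 3107 were unchanged in call, 84 lost the call and 2 reversed, both with at least 500 genes per nucleus. These were Penk in corticospinal-like neurons, at 0.045, and Met in hindbrain glutamatergic-like neurons, at -1.90. Under that limit low-gene barcodes of replicate 2, which may hold free RNA, were added. Hypothalamus-like neurons also fell out of the fit, so the reference changed along with the nuclei. In the main fit that class held Penk at a higher level and had no UMI of Met. Which of these changes moved the values was not tested. Calls were lost by size or test in corticospinal-like neurons for Tac1 without replicate 3 (log2 fold change -0.86), in hypothalamus-like neurons for Scn8a without replicate 3 (-0.98), Cacna2d2 without replicate 2 (-0.94) and Vgf without replicate 1 (0.86) or 2 (0.82), and in red nucleus-like neurons for Grin2b without replicate 3 (-0.96), Scg2 without replicate 1 (-0.96) or 2 (-0.91) and Nucb2 without replicate 2 (-0.68).

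Without the filter on low counts, 1527 genes were higher in corticospinal-like neurons and 2 lists were higher in hindbrain glutamatergic-like neurons, with 13955 held-out genes tested in place of 8066. In the 2-group fit 854 genes were lower in hypothalamus-like, 792 lower in red nucleus-like, and 1317 higher and 1037 lower in hindbrain glutamatergic-like neurons. With variable genes from all genes, 292 were higher and 148 lower in hindbrain glutamatergic-like neurons, whose share was 22.5%. An inhibitory-like class with 5.38% of nuclei then entered the fit. With at least 500 genes per nucleus, hypothalamus-like neurons fell out of the fit. No comparison of that class could be made, and the other classes lacked it in their reference. There 365 genes were lower in hindbrain glutamatergic-like neurons. The shares were 55.3% corticospinal-like, 8.59% hindbrain glutamatergic-like, 0.636% hypothalamus-like, 0.722% noradrenergic-like and 31.2% unnamed. The corticospinal-like share was 32.5%, 84.1% and 49.3% in replicates 1, 2 and 3. Low-gene barcodes of replicate 2, which may hold free RNA, enter at this limit. With unnamed clusters added, 353 genes were higher in hindbrain glutamatergic-like neurons. With an estimated correlation (camera) 0 lists were higher in corticospinal-like, 0 higher and 0 lower in hypothalamus-like, 0 higher in red nucleus-like, and 1 higher and 0 lower in hindbrain glutamatergic-like neurons. At an unadjusted p under 0.05 these were 4 higher, 1 higher and 3 lower, 1 higher, and 5 higher and 2 lower. At resolution 2 the shares were 24.9% corticospinal-like, 27.9% hindbrain glutamatergic-like, which was then the largest named class, and 39.5% unnamed, and at resolution 0.5 19.3% hindbrain glutamatergic-like and 29.6% unnamed. With at least 2000 genes per nucleus 1.00% were serotonergic-like and 11.5% unnamed, and with the limit of 500 leading genes 14.8% were unnamed. For the values in this paragraph the cause was not tested.

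Without each replicate in turn, 961 to 1106 genes were higher and 1064 to 1108 lower in corticospinal-like, 452 to 493 and 374 to 392 in hypothalamus-like, 392 to 444 and 276 to 333 in red nucleus-like, and 471 to 571 and 166 to 202 in hindbrain glutamatergic-like neurons. In the same order 3 to 5, 0 to 1, 1 to 2 and 4 to 6 lists were higher and 0, 3, 0 to 1 and 1 to 2 lower. The 0 higher in hypothalamus-like neurons came without replicate 2 (camera, 1 at an unadjusted p under 0.05), and the 2 higher and 1 lower in red nucleus-like neurons and the 1 lower in hindbrain glutamatergic-like neurons without replicate 1. The mean shares were 39.8 to 49.1%, 1.91 to 2.78%, 3.58 to 4.92% and 25.5 to 30.6%, with 0.430 to 0.607% noradrenergic-like, 0.357 to 0.469% serotonergic-like and 18.9 to 22.8% unnamed. Without the replicate block, 935 and 1131 genes were higher and lower in corticospinal-like, 509 and 386 in hypothalamus-like, 428 and 316 in red nucleus-like and 467 and 194 in hindbrain glutamatergic-like neurons. That fit ended the calls of 2 lists, axon guidance receptors and growth-associated genes in hindbrain glutamatergic-like neurons, and of 1 named gene result, Nucb2 in red nucleus-like neurons, and no other of the 17 list and 191 gene calls. DESeq2, its size factors, values centred within libraries and doublets kept moved no count of genes by over 1.5 times. The hypothalamus-like sums held the fewest UMIs of the 4 main classes, and simulated changes were recovered least often there (80.4% at 4-fold and 24.2% at 2-fold).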

Other observations

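The control of the depth test with 1 fraction of UMIs per nucleus and the counts at an unadjusted p in the splits were chosen only after the results were seen, and the other tests below were planned.

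Further genes of noradrenergic-like and serotonergic-like neurons are given as values with no test, and were chosen after they were seen. In noradrenergic-like neurons the cell adhesion gene Sdk1 stood at 2404 ± 327 CPM against 231 ± 11.6 CPM, the thyrotropin receptor gene Tshr at 110.3 ± 62.5 CPM against 3.49 ± 0.914 CPM and Pdlim5 at 223 ± 49.5 CPM against 13.9 ± 2.07 CPM in the main classes. In serotonergic-like neurons Pappa2, a protease gene of the insulin-like growth factor system, stood at 160.1 ± 79.2 CPM against 4.28 ± 1.47 CPM and Cpa6, which encodes a carboxypeptidase, at 606 ± 689.5 CPM against 14.6 ± 3.54 CPM (SD, n = 3 libraries), where the SD of Cpa6 exceeds its mean.

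Other splits of the 12 class sums were counted as 64 sets of 1 sum per library, each against the other 9 sums. The corticospinal-like set gave 2041 calls, with 253 the highest other count. The hypothalamus-like, red nucleus-like and hindbrain glutamatergic-like sets gave 253, 61 and 35, with 2041 the highest other count for each. As many calls were reached by 1, 2, 3 and 4 of the 64 sets in the same order, and these were the sets of the 4 classes themselves. The counts therefore give only the order of the classes, and 64 sets are too few for a share under 0.05 in the class that comes last. The 60 sets that mix classes gave 0 calls each (edgeR). At an unadjusted p under 0.05 they held 6 to 1369 held-out genes, against 4505, 1598, 926 and 655 in the classes. A mixed set puts different classes in the same group, so class differences add to the spread within groups and hold calls down. The 0 calls therefore do not measure how many calls arise by chance.

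Within the corticospinal-like class, cluster 0 took 74.9% of its nuclei from replicate 3 and cluster 1 85.4% from replicate 2. After each nucleus was thinned to 5000 UMIs, which left out 60, 12 and 8 nuclei of replicates 1, 2 and 3, the adjusted mutual information of cluster and library was 44.6% of its value at full depth, as a difference in depth predicts. Thinning to 1 fraction of 20.1% of the UMIs, which keeps the depth difference, left 113%. The replicate 2 to replicate 3 differences of 3358 held-out genes in corticospinal-like neurons correlated with those in hindbrain glutamatergic-like neurons at r = 0.673 across genes, which are not independent replicates, as a library difference shared by both classes predicts. With red nucleus-like and hypothalamus-like neurons r was 0.474 and 0.334. Depth and a shared library difference may both contribute, and no biological explanation was tested, since the libraries form 1 group.

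Xist, which is transcribed from the inactive X chromosome, had a UMI in 94.0%, 94.1% and 94.8% of barcodes within the gene and mitochondrial limits in replicates 1, 2 and 3. In the same barcodes, doublets and non-neuronal nuclei included, the Y-linked genes Ddx3y and Uty had 1, 1 and 0 and 4, 17 and 14 UMIs per library.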
